A study of Homo sapiens with 6 samples.

How the data were processed

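RNA sequencing libraries from Huh7, a human hepatocellular carcinoma cell line, were compared between cells infected with a FLAG control lentivirus and cells infected with a lentivirus carrying VPS72, with 3 libraries per group. Virus made in HEK293T cells was left on the cells for 24 h, per the labels. RNA was isolated with RNAzol and libraries were made with the KAPA RNA HyperPrep kit, per the labels' protocols. Whether ribosomal RNA was depleted or polyadenylated RNA selected, and whether the kit's strand information was used in counting, is not given in the sources used here. The groups and replicate numbers were taken from the sample titles. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

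The authors deposited 1 table of gene-level values, with 37822 gene symbols and 1 column per library. The authors deposited estimated counts per gene, as whole numbers and not normalized, from processing for which the submitters' processing notes name STAR, RSEM and limma. This unit was read from the values, which are whole numbers with different library totals and in which near-identical gene pairs such as SMN1 and SMN2 both hold reads. The notes give these tools and the builds hg19 and hg38 without role or order, so the build behind the table is not given here and no coordinates are printed. Tool versions, the annotation and the step that made the values whole are not given in the sources used here. An estimating counter divides reads between similar genes, so values of near-identical paralogs such as the metallothioneins are less certain than those of single-copy genes, as are those of overlapping or antisense genes.

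Total counts ranged from 21345279 to 29091824 per library. Genes were filtered with filterByExpr by group (a minimum count of 10 and a minimum total of 15), which left 14253 genes holding 99.925% of the counts. Library sizes were scaled with TMM, and VPS72 was compared with FLAG by edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic. CPM values use the TMM-scaled library size and are given as mean ± SD over 3 libraries. The common coefficient of variation between libraries of a group was 7.24%. Libraries of a group differed from each other by more than sampling noise, with a chi-square per degree of freedom of 4.73 to 7.78 over genes with at least 20 counts in a pair, so none was treated as a second deposit of another library. This does not show that they came from separate cultures. Where a comparison of a single value would need an exact permutation test, 3 samples against 3 cannot give a p below 0.1.

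The comparison, the tests, 24 gene lists and the rule for the named genes were fixed before the data were examined. The lists cover de novo lipogenesis, cholesterol synthesis, fatty acid oxidation, lipid droplets, mTORC1 regulators, the integrated stress response, endoplasmic reticulum chaperones, AP-1 and immediate early genes, the SRCAP and TIP60 complexes, interferon-stimulated genes, NF-kB targets, the cell cycle, p53 targets, hepatocyte genes, glycolysis and hypoxia, oxidative phosphorylation, lysosome and autophagy, ribosomal proteins, mitochondrially encoded mRNAs, replication-dependent histones, and markers of HEK293T cells, fibroblasts, immune cells and endothelial cells. All 491 list entries were found in the table, 1 of them under an older symbol through the RefSeq gene table of GRCh38.p14, which was used only for names and for which genes lie next to VPS72. A list was compared with the other tested genes by limma's camera (limma 3.58.1) with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 23 lists with at least 3 tested members. The same lists were tested with the correlation estimated per list and with fry. Named genes were VPS72, ATF3 and SREBF1. To these were added the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold, with a mean of at least 5 CPM and with no overlap between the groups, VPS72 left out. Of each list, up to 4 members past the threshold with the smallest p were named, or up to 2 of the most abundant members where none passed. Some genes the rule takes are not reported here by name, and counts include them. Any other gene named was chosen after its values were seen.

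The alternatives were DESeq2 size factors, library size only and upper quartile scaling, no filter and a stricter filter on low counts, DESeq2 (1.42.0), limma-voom, the replicate number as a block, VPS72 or abundant RNA left out of the library size, libraries thinned to 1 depth, a threshold of 0.01, a test against a 1.5-fold change, and each library left out in turn. A smooth trend with abundance, or with GC content and transcript length, was removed per library in alternatives chosen after seeing the data, as was DESeq2 without independent filtering. GC content, length and 3′ UTR sequence came from GENCODE 29 gene models matched by symbol, which gave a length and GC content for 98% of the tested genes.

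The tests were tested on simulated data drawn from the means, library sizes and dispersions of these 6 libraries, with 200 genes changed. These were picked at random from the tested genes outside the lists. Over 20 draws, edgeR recovered 1.6% of genes changed 1.1-fold, 23.5% of those changed 1.2-fold, 58.9% of those changed 1.5-fold and 77.2% of those changed 2-fold, among 14200 to 14246 genes tested. Of its calls, 10.1% were false. In 20 draws with no change, camera with the preset correlation called 1 of 460 lists and with the estimated correlation 0. A list raised 1.1-fold was called in 20 of 20 draws with the preset and in 4 of 20 with the estimated correlation. Each gene was drawn independently, so these rates hold only for lists without correlation between members. They do not show how the preset performs on correlated lists. In other splits of the 6 real libraries into 3 and 3, the preset called up to 6 lists and the estimated correlation 0. In the real data the estimated correlation was 0.21 for the AP-1 list and 0.67 for the mitochondrially encoded list.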

Results

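The libraries of Huh7 cells held 25352335, 25184930 and 21345279 counts in FLAG replicates 1 to 3 and 29091824, 26694675 and 23969324 in VPS72 replicates 1 to 3. Mitochondrially encoded mRNAs took 10.5% to 11.2% of each library. Mitochondrial ribosomal RNA varied between libraries with no order by group, from 172 CPM of the unscaled total in VPS72 replicate 1 to 1491 CPM in VPS72 replicate 2. MALAT1, a nuclear long non-coding RNA, took 4419 to 4569 CPM of the unscaled totals in FLAG and 4193 to 4334 CPM in VPS72 libraries (log2 fold change after TMM scaling -0.05 ± 0.02; edgeR, Benjamini-Hochberg adjusted p = 0.333), and TMM factors were 1.008 to 1.013 in FLAG and 0.989 to 0.990 in VPS72 libraries.

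The comparison asked what a raised level of VPS72, a subunit of the SRCAP and TIP60 chromatin complexes that handles the histone variant H2A.Z, does to the transcripts of liver cancer cells, with ATF3, mTORC1 and SREBP1-driven lipid synthesis as the pathway of interest. VPS72 mRNA was 48.5-fold higher in the VPS72 libraries, at 1162 ± 11.5 CPM against 24.0 ± 2.70 CPM in the FLAG libraries (SD, n = 3 per group). ATF3, a stress-induced transcription factor of the AP-1 and ATF families, fell by 44.6%, from 32.6 ± 2.96 to 18.1 ± 1.16 CPM. SREBF1, which encodes SREBP1, stood at 93.5 ± 7.31 CPM against 92.0 ± 8.48 CPM and did not pass the test. These are mRNA levels, and the activity of SREBP1 protein and of mTORC1 was not measured in these data. Genes of cholesterol synthesis, de novo lipogenesis, the cell cycle and hepatocyte secretion were higher as lists, with list medians from 6.31% to 13.9%.

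For VPS72 itself, counts ran from 511 to 686 in the FLAG libraries and from 27483 to 33086 in the VPS72 libraries, in the direction of the labels. Its log2 fold change was 5.60 ± 0.06 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.85e-18). For ATF3 the log2 fold change was -0.85 ± 0.09 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.000362), lower in 3 of 3 VPS72 libraries. In the test against a 1.5-fold change VPS72 passed and no other gene did, ATF3 included. For SREBF1 it was 0.02 ± 0.07 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.943), and its sign turned with library size scaling alone (-0.01), without FLAG replicate 2 (-0.05), without VPS72 replicate 2 (-0.01) and without VPS72 replicate 3 (-0.01). Of the protein-coding genes next to VPS72 on the reference genome (GRCh38.p14), up to 5 on either side, 8 were tested and 0 changed by edgeR, the smallest Benjamini-Hochberg adjusted p being 0.33.

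**Figure D1:**
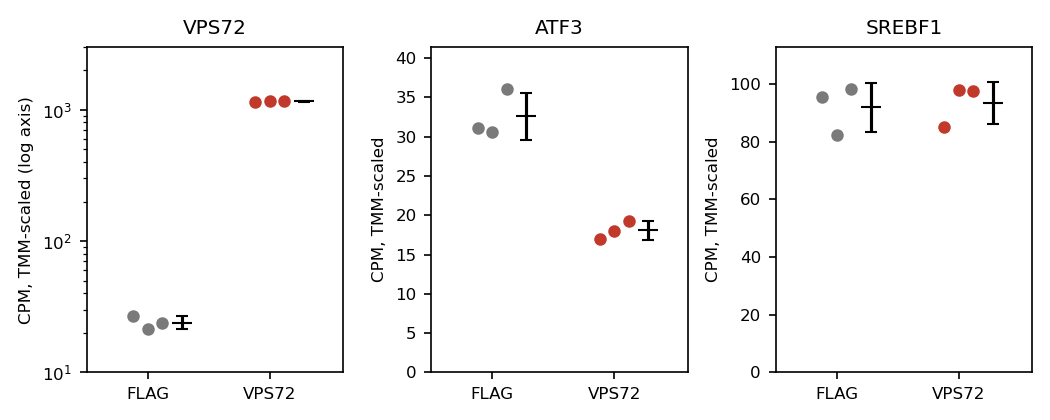
TMM-scaled CPM of VPS72 (log axis), ATF3 and SREBF1 (axes from 0) in each of the 3 FLAG and 3 VPS72 libraries, drawn as points, with the group mean and SD as bars. VPS72 lies at 21.4 to 26.7 CPM in FLAG and 1150 to 1173 CPM in VPS72 libraries, ATF3 is lower in every VPS72 library, and the SREBF1 groups overlap.

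Across 14253 genes tested, 88 changed, 60 higher and 28 lower with VPS72, and 1645 passed an unadjusted p of 0.05. Besides VPS72, 1 gene changed at least 2-fold. It was ANO9, a member of the anoctamin family, which fell by 64.4% from 5.82 ± 0.55 to 2.06 ± 0.43 CPM and is named after its values were seen, since its mean of 3.94 CPM is below the level set for named genes. The median rise among the 59 higher genes other than VPS72 was 15.9%, at a median abundance of 296 CPM. The median change of the 28 lower genes was -23.6%, at 48.9 CPM, against 21.3 CPM for all tested genes. All 88 genes had no overlap between the groups, as had 17.2% of tested genes, where chance gives 10%. Fold changes rose with abundance, from a median of -0.10 below a log2 CPM of 1 to 0.06 above 9. The balance of directions depended on scaling. Library size alone gave 32 higher and 54 lower, upper quartile scaling 44 and 32, removal of the abundance trend 27 and 27, and removal of the GC and length trend 324 and 67. Library size alone also lowered the median log2 fold change of all tested genes from -0.00 to -0.04, and every list's median with it. Leaving out single libraries gave 25 changed genes without FLAG replicate 1, 100 without FLAG replicate 2, 42 without FLAG replicate 3, 35 without VPS72 replicate 1, 52 without VPS72 replicate 2 and 56 without VPS72 replicate 3. Without a filter on low counts 264 genes changed, with DESeq2 268.

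**Figure D2:**
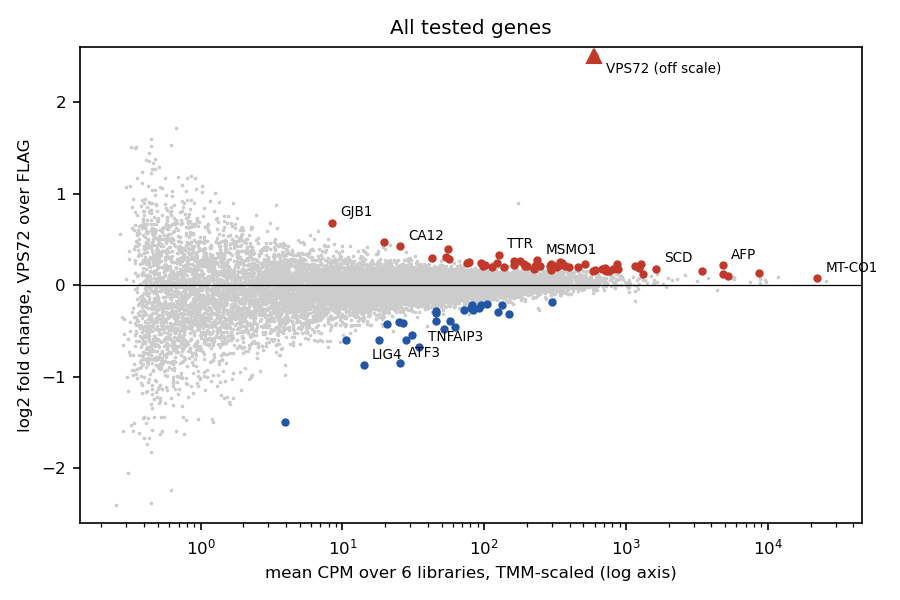
Mean TMM-scaled CPM over the 6 libraries (log axis) against the log2 fold change of VPS72 over FLAG for every tested gene. Genes past an adjusted p of 0.05 are red (60 higher) or blue (28 lower), others are grey, and the triangle marks VPS72 at 5.60, beyond the axis. The higher genes lie mostly to the right of the lower ones.

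Among the 10 largest rises, GJB1, the gap junction protein connexin 32 of hepatocytes, went from 6.45 ± 0.60 to 10.4 ± 1.52 CPM (log2 fold change 0.68 ± 0.14). GPR160, an orphan receptor, rose by 0.48 ± 0.09 on the log2 scale, and CA12, a membrane carbonic anhydrase, by 0.42 ± 0.08. FBLN5, an elastic fibre protein, rose by 0.40 ± 0.06, and TTR, the liver-made thyroxine carrier transthyretin, by 0.34 ± 0.05. TTN rose by 0.30, CCNB2 by 0.29, CCDC80 by 0.29, MSMO1 by 0.28 and INSIG1 by 0.26. All 10 were higher in 3 of 3 VPS72 libraries, with Benjamini-Hochberg adjusted p from 0.00246 for TTR to 0.0441 for GJB1 in edgeR's quasi-likelihood test. Calls of FBLN5, TTR and MSMO1 held without any single library. Those of the other 7 were lost without FLAG replicate 1, as in GJB1 (adjusted p = 0.172), CCNB2 (0.21), CA12 (0.137), CCDC80 (0.237), TTN (0.164), INSIG1 (0.18) and GPR160 (0.124), by the same test, and each of them in 4 to 6 of the 6 leave-outs. By that test the adjusted p was also above the threshold with library size alone for GJB1 (0.0544), CCNB2 (0.0685), CCDC80 (0.0746) and TTN (0.0529), with upper quartile scaling for CCDC80 (0.0502), in libraries thinned to 1 depth for GJB1 (0.0633) and CCNB2 (0.0509), and with the abundance trend removed for CCNB2 (0.0509), CCDC80 (0.0613) and INSIG1 (0.0509). GJB1 had 0.0558 with limma-voom. The same 7 calls were lost with the replicate number as a block, which leaves fewer residual degrees of freedom, with edgeR's adjusted p from 0.071 for INSIG1 to 0.124 for CCNB2.

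The 10 largest falls included ATF3. LIG4, the ligase of non-homologous end joining, fell by 45.4%, from 18.3 ± 0.83 to 9.97 ± 1.19 CPM (log2 fold change -0.87 ± 0.11). TNFAIP3, the NF-kB inhibitor A20, fell by 37.3% (-0.67 ± 0.08) and GADD45A, a growth arrest and DNA damage gene, by 34.1% (-0.60 ± 0.10). FGFR1, a growth factor receptor, had a log2 fold change of -0.60. MT2A, a metal-binding metallothionein, fell by 31.5% (-0.54 ± 0.09). SLC7A11, the cystine transporter, fell by 28.3% from 60.5 ± 0.51 to 43.4 ± 1.37 CPM, and KLF10, a TGF-beta induced transcription factor, by 27.2%. DTX3 fell by 25.3%. Benjamini-Hochberg adjusted p in edgeR's quasi-likelihood test ran from 0.000362 for ATF3 to 0.0441 for DTX3, and each gene was lower in 3 of 3 VPS72 libraries. The falls of ATF3, LIG4, TNFAIP3, MT2A, SLC7A11 and KLF10 passed without any single library. Without FLAG replicate 1 the adjusted p was 0.115 for GADD45A, 0.159 for FGFR1 and 0.261 for DTX3 by the same test, and these calls were lost in 3, 4 and 5 of the 6 leave-outs. With the abundance trend removed it was 0.0613 for FGFR1 and 0.0715 for DTX3, and with the replicate number as a block 0.0744 for FGFR1 and 0.0995 for DTX3. Of the 33 named genes past the threshold, 16 passed without FLAG replicate 1, 30 without FLAG replicate 2, 21 without FLAG replicate 3, and 18, 22 and 24 without VPS72 replicates 1, 2 and 3.

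Cholesterol synthesis genes were higher. Of 25 tested members of the SREBP2 target list, 7 rose, 0 fell and 18 did not pass, and 17 rose when adjusted over the list alone. MSMO1, a sterol demethylating oxidase, rose by 21.2% from 214 ± 6.53 to 259 ± 9.33 CPM, INSIG1, the sterol sensor that retains SREBP in the endoplasmic reticulum, by 19.9%, FDFT1, squalene synthase, by 17.5%, and DHCR7, the last reductase of the pathway, by 17.1%. SREBF2, which encodes SREBP2, had a log2 fold change of 0.01 ± 0.04 that did not pass. The list's median was 0.15, with camera's Benjamini-Hochberg adjusted p = 7.95e-11, and adjusted p = 0.0468 with an estimated correlation. Without FLAG replicate 1, edgeR's Benjamini-Hochberg adjusted p was 0.18 for INSIG1, 0.164 for FDFT1 and 0.0566 for DHCR7, and with the abundance trend removed 0.0509 for INSIG1 and 0.0529 for FDFT1. The calls of INSIG1 and FDFT1 were lost in 4 and 3 of the 6 leave-outs. Both were also lost with the replicate number as a block (edgeR, Benjamini-Hochberg adjusted p = 0.071 and 0.0835).

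De novo lipogenesis genes were higher as a list. Of 21 tested members, 3 rose, 0 fell and 18 did not pass, and 6 rose when adjusted over the list alone. SCD, the stearoyl-CoA desaturase, rose by 13.3% from 1523 ± 12.3 to 1726 ± 21.8 CPM, ACLY, which makes cytosolic acetyl-CoA from citrate, by 14.4%, and GPAM, the first acyltransferase of glycerolipid synthesis, by 18.2%. FASN, the fatty acid synthase, had a log2 fold change of 0.09 ± 0.09 and did not pass, with a wide spread in both groups (911 ± 116 and 969 ± 145 CPM). The list's median was 0.09, with camera's Benjamini-Hochberg adjusted p = 1.61e-05, and adjusted p = 0.0468 with an estimated correlation. The median was 0.06 with library size alone, 0.06 with the abundance trend removed and 0.14 with the GC and length trend removed. The SCD call held without any single library. That of ACLY was lost without FLAG replicate 1 (edgeR, Benjamini-Hochberg adjusted p = 0.124) or VPS72 replicate 1 (0.0848). It was also lost with the replicate number as a block (0.0835) and with the abundance trend removed (0.0715). The GPAM call was lost in all 6 leave-outs, with adjusted p up to 0.221 without FLAG replicate 1. It was also lost with the replicate number as a block (0.133), the abundance trend removed (0.0715), library size alone (0.0917), upper quartile scaling (0.0524), libraries thinned to 1 depth (0.0525) and limma-voom (0.0513).

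Other lipid lists did not pass with all 6 libraries. Of 14 tested lipid droplet and triglyceride storage genes, 0 passed over all genes and 1, PLIN3, over the list alone, with a list median of 0.09 and camera's Benjamini-Hochberg adjusted p = 0.0673. That p was 0.0494 without VPS72 replicate 3, and with all libraries adjusted p = 0.348 with an estimated correlation. The median lay at percentile 99.31 of those of expression-matched random lists, and was 0.05 with library size alone. PLIN2, the main lipid droplet coat protein of hepatocytes, had a log2 fold change of 0.08 ± 0.03 and MGLL, monoacylglycerol lipase, of 0.08 ± 0.04. Of 19 fatty acid oxidation genes, 0 passed either way, with a median of 0.01 that turned to -0.02 with library size alone, and camera's Benjamini-Hochberg adjusted p = 0.453. HADHA, the mitochondrial trifunctional protein subunit, had a log2 fold change of 0.05 ± 0.04.

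Hepatocyte secreted proteins were higher. Of 23 tested genes of the hepatocyte list, 10 rose, 0 fell and 13 did not pass, and 17 rose when adjusted over the list alone. AFP, the fetal albumin homologue made by this cell line, rose by 16.1% from 4464 ± 82.0 to 5184 ± 98.4 CPM (log2 fold change 0.22 ± 0.02; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 5.89e-05). SERPINA1, alpha-1-antitrypsin, rose by 17.7%, FGB, a fibrinogen chain, by 17.6%, and ALB, albumin, by 11.6%. The median was 0.19, where expression-matched random lists had a median of 0.03, with camera's Benjamini-Hochberg adjusted p = 1.09e-12, and adjusted p = 0.0263 with an estimated correlation. The call of ALB was lost with the abundance trend removed (log2 fold change 0.08; edgeR, Benjamini-Hochberg adjusted p = 0.0964).

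All 24 cell cycle genes had a positive log2 fold change, with a median of 0.11. Over all genes, 1 rose, CCNB2 (cyclin B2), by 22.7% from 38.4 ± 1.35 to 47.1 ± 0.82 CPM, and 23 did not pass, while 12 rose when adjusted over the list alone, among them TOP2A (0.15 ± 0.04) and MKI67 (0.13 ± 0.03). Camera's Benjamini-Hochberg adjusted p was 3.11e-09, and adjusted p = 0.0468 with an estimated correlation. The CCNB2 call was lost in all 6 leave-outs, with edgeR's Benjamini-Hochberg adjusted p up to 0.21 without FLAG replicate 1. For the cholesterol, lipogenesis, hepatocyte and cell cycle lists, the estimated correlation together with removal of the abundance trend gave adjusted p from 0.0785 to 0.0924.

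**Figure D3:**
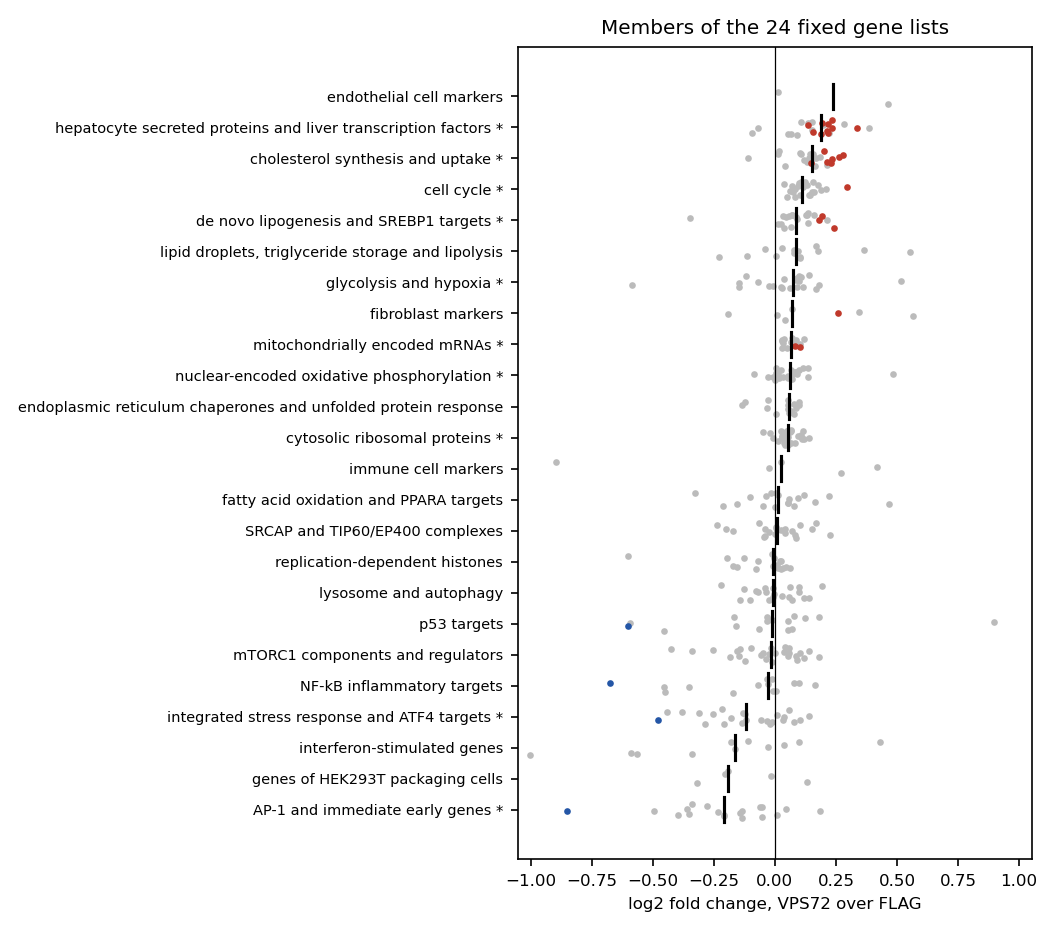
Log2 fold change of VPS72 over FLAG for each tested member (points) of the 24 lists, with the list median as a black bar. Red points rose and blue points fell at an adjusted p of 0.05 over all genes, and a star marks the 10 lists past camera's threshold with the preset correlation. The hepatocyte list has a median of 0.19 and the AP-1 list of -0.21.

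The AP-1 and integrated stress response lists lay lower, each with 1 gene past the threshold over all genes, and neither passed with an estimated correlation. Of 19 tested AP-1 and immediate early genes, 1, ATF3, fell and 18 did not pass, and 7 fell when adjusted over the list alone, including FOSL2 (-0.28 ± 0.06) and MYC (-0.21 ± 0.07). The median was -0.21, with camera's Benjamini-Hochberg adjusted p = 0.000412, and adjusted p = 0.354 with an estimated correlation. Of 24 integrated stress response and ATF4 target genes, 1, SLC7A11, fell and 23 did not pass, and 4 fell when adjusted over the list alone, among them SESN2 and GDF15. That list's median was -0.12, with camera's Benjamini-Hochberg adjusted p = 0.00683, and adjusted p = 0.174 with an estimated correlation. By fry the integrated stress list passed (Benjamini-Hochberg adjusted p = 0.0239) and the AP-1 list did not (0.0885). ATF4 itself (-0.03 ± 0.05) and TRIB3 (-0.02 ± 0.05) did not pass.

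Of 27 mTORC1 components and regulators, 0 passed over all genes and 1 fell over the list alone, SESN2, an amino acid sensor that restrains mTORC1 (-0.25 ± 0.07). MTOR had a log2 fold change of 0.06 ± 0.04 and TSC1 of -0.10 ± 0.04, and the list's median was -0.01 (camera, Benjamini-Hochberg adjusted p = 0.51), which was 0.00 with the GC and length trend removed. The mRNA levels of these components do not show whether mTORC1 activity changed. Among 14 NF-kB targets, TNFAIP3 fell and 13 did not pass, with 2 lower over the list alone, TNFAIP3 and RELB, and a median of -0.03 (camera, Benjamini-Hochberg adjusted p = 0.0801). That p was 0.031 without FLAG replicate 1 and 0.0328 with limma-voom, against adjusted p = 0.467 with an estimated correlation. Of 17 p53 targets, GADD45A fell and 16 did not pass, 1 fell over the list alone, and the median of -0.01 (camera, Benjamini-Hochberg adjusted p = 0.51) turned to 0.01 with the GC and length trend removed. Of 16 endoplasmic reticulum chaperone genes, 0 passed either way, with a median of 0.06 (camera, Benjamini-Hochberg adjusted p = 0.0541, 0.0338 without FLAG replicate 2, 0.00953 with limma-voom and 0.0288 with the GC and length trend removed). With an estimated correlation the chaperone list had adjusted p = 0.422, and adjusted p = 0.42 with the GC and length trend also removed. HSP90B1 had a log2 fold change of 0.08 ± 0.03 and CALR of 0.08 ± 0.03, and HSP90B1 passed with DESeq2 (Benjamini-Hochberg adjusted p = 0.0478) and with the GC and length trend removed (edgeR, 0.0189). Of 11 interferon-stimulated genes, 0 passed either way, with a median of -0.16 (camera, Benjamini-Hochberg adjusted p = 0.797) that was -0.09 with the abundance trend removed, and ISG15 at -0.18 ± 0.23.

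The complexes that contain VPS72 did not pass as a list. Of 22 SRCAP and TIP60 complex genes, 0 passed over all genes, while over the list alone 1 rose, H2AZ1, which encodes H2A.Z (0.22 ± 0.05), and 1 fell, EPC1 (-0.20 ± 0.05). H2AZ2 had a log2 fold change of 0.03 ± 0.04 and EP400 of -0.04 ± 0.05. The median of 0.01 (camera, Benjamini-Hochberg adjusted p = 0.51) turned to -0.02 with library size alone and -0.00 with the abundance trend removed.

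Lists of abundant housekeeping transcripts lay slightly higher, and none of them held with an estimated correlation. Of 33 ribosomal protein genes, 0 passed either way, with a median of 0.05 and camera's Benjamini-Hochberg adjusted p = 0.00208 (adjusted p = 0.489 with an estimated correlation). RPL15 had a log2 fold change of 0.06 ± 0.04 and RPS2 of 0.06 ± 0.03. Of 26 nuclear-encoded oxidative phosphorylation genes, 0 passed either way, with a median of 0.06 and camera's Benjamini-Hochberg adjusted p = 0.00845 (adjusted p = 0.194 with an estimated correlation), ATP5F1B at 0.11 ± 0.04 and NDUFS1 at 0.03 ± 0.04. Of 22 glycolysis and hypoxia genes, 0 passed over all genes and 3 rose over the list alone, with a median of 0.08 and camera's Benjamini-Hochberg adjusted p = 0.0497 (adjusted p = 0.485 with an estimated correlation), GAPDH at 0.11 ± 0.03 and PKM at 0.09 ± 0.03. With the GC and length trend removed GAPDH, PKM and ATP5F1B passed (edgeR, Benjamini-Hochberg adjusted p = 0.00497, 0.0234 and 0.038), as did GAPDH and ATP5F1B with DESeq2 (0.015 and 0.0348), and GAPDH without a filter on low counts (0.000788), without FLAG replicate 2 (0.0415) and without VPS72 replicate 3 (0.042). Among 13 mitochondrially encoded mRNAs, MT-CO1 rose by 5.79% and MT-ND1 by 7.26%, 11 did not pass and 6 rose over the list alone. The MT-ND1 call was lost in 5 of 6 leave-outs (edgeR, Benjamini-Hochberg adjusted p up to 0.152 without FLAG replicate 1), with library size alone (0.138), with upper quartile scaling (0.0808) and with the abundance trend removed (log2 fold change 0.01, adjusted p = 0.846), and that of MT-CO1 without VPS72 replicate 2 (0.0535). With the replicate number as a block both calls were lost (edgeR, 0.136 for MT-ND1 and 0.0516 for MT-CO1). That list's median was 0.07, with camera's Benjamini-Hochberg adjusted p = 0.00395 (adjusted p = 0.485 with an estimated correlation). With the abundance trend removed the median was -0.03 and MT-CO1 stood at -0.03, while the ribosomal protein median was 0.02 (camera, Benjamini-Hochberg adjusted p = 0.347) and the glycolysis median 0.03 (0.178). In that fit the oxidative phosphorylation list kept a median of 0.06 and passed camera with the preset correlation (0.0279), but not with an estimated one (0.26). With library size alone the medians were 0.02 for ribosomal protein, 0.03 for oxidative phosphorylation, 0.04 for glycolysis and 0.04 for mitochondrially encoded genes. The mitochondrially encoded list's p was 0.104 without FLAG replicate 2 and 0.0543 without VPS72 replicate 1. Ribosomal protein genes gave 0.0712 without FLAG replicate 1 and 0.0543 without VPS72 replicate 1, and oxidative phosphorylation genes 0.0556 without FLAG replicate 1, by the same test. The glycolysis list passed only without FLAG replicate 2 or VPS72 replicate 3 among the leave-outs, and reached 0.234 without VPS72 replicate 2. It did not pass with library size alone (0.0607), upper quartile scaling (0.056), no filter on low counts (0.101) or the stricter filter (0.0509).

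Of 21 lysosome and autophagy genes, 0 passed over all genes and 1, CTSB, rose over the list alone, with a median of -0.01 that turned to 0.01 with the GC and length trend removed, a mean of 0.00 and camera's direction upward (Benjamini-Hochberg adjusted p = 0.51). SQSTM1 had a log2 fold change of 0.03 ± 0.03 and LAMP1 of 0.06 ± 0.03. Of 18 replication-dependent histone genes, 0 passed either way, with a median of -0.01 (camera, Benjamini-Hochberg adjusted p = 0.51), H3C2 at 0.01 ± 0.08 and H2BC21 at 0.04 ± 0.04.

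Lists of markers of other cells did not pass, except fibroblast markers with limma-voom (camera, Benjamini-Hochberg adjusted p = 0.0405). Of 7 tested fibroblast markers, LUM, the matrix proteoglycan lumican, rose by 19.7% (log2 fold change 0.26 ± 0.04) and 6 did not pass, with 1 higher over the list alone and a median of 0.07 (camera, Benjamini-Hochberg adjusted p = 0.0826, and adjusted p = 0.381 with an estimated correlation). The LUM call was lost without FLAG replicate 1 (edgeR, Benjamini-Hochberg adjusted p = 0.0773). Of 5 tested HEK293T genes, 0 passed either way, with a median of -0.19 (camera, Benjamini-Hochberg adjusted p = 0.326), HOXC10 at -0.21 ± 0.11 and HOXA10 at -0.01 ± 0.12. Of 5 immune cell markers, 0 passed either way, with a median of 0.02 that turned to -0.01 with library size alone, a mean of -0.04 and camera's direction upward (Benjamini-Hochberg adjusted p = 0.17), LYZ at 0.27 ± 0.11 and CD3D at 0.42 ± 0.23. Of the endothelial markers, 2 were tested and neither passed, EGFL7 at 0.01 ± 0.30 and PECAM1 at 0.46 ± 0.22, too few for a list test.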

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

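Removal of the abundance trend, removal of the GC and length trend, both with an estimated correlation, and DESeq2 without independent filtering were chosen after the results were seen. VPS72 and ATF3 kept their direction and passed in the 19 alternatives that gave each an adjusted p against no change, at log2 fold changes of 5.52 to 5.69 and -0.90 to -0.77. SREBF1 passed in none, at -0.0497 to 0.0936 with a library left out and -0.00764 with library size alone. Against 88 genes changed, 60 higher, 28 lower and 2 at least 2-fold, no low-count filter gave 264, 166, 98 and 13, and DESeq2 268, 209, 59 and 1. DESeq2's independent filtering left an adjusted p for 5169 genes, not for 14 of the 88, and none of the other 74 lost its call. Without that filtering DESeq2 gave 173 genes, 129 higher and 44 lower, and kept all 88. Limma-voom gave 128, 92 of them higher, library size alone 32 higher and 54 lower, a threshold of 0.01 gave 32 genes, and the test against a 1.5-fold change 1, VPS72, so ATF3 did not pass it. Removal of the abundance trend gave 54 genes, 27 of them higher, and kept 50 of the 88. Removal of the GC and length trend gave 391, 324 higher, 67 lower and 5 at least 2-fold, and kept all 88. Leaving out 1 library gave 25 to 100 genes, 15 to 61 higher, 9 to 39 lower and 2 to 4 at least 2-fold, with fewer samples and residual degrees of freedom. The replicate number as a block gave 32 genes, 18 higher and 14 lower, all among the 88, and 19 of the 33 named genes. The block leaves fewer residual degrees of freedom, so a call lost under it does not by itself point to a batch. The named calls lost were ACLY, CA12, CCDC80, CCNB2, DTX3, FDFT1, FGFR1, GJB1, GPAM, GPR160, INSIG1, MT-CO1, MT-ND1 and TTN (edgeR, Benjamini-Hochberg adjusted p 0.0516 to 0.136). Same-numbered libraries had correlations of -0.28, -0.15 and 0.15 in their deviations from the group means, so the numbers were not taken to pair the samples. Libraries of unlike number ran from -0.31 (FLAG replicate 2 with VPS72 replicate 3) to 0.427 (FLAG replicate 2 with VPS72 replicate 1). Some variation was thus shared across the groups, and its source was not tested. With a library left out, 16 to 30 named genes passed. Of the 33, 14 passed in every alternative with an adjusted p against no change and 19 were lost in at least 1, while 18 passed the threshold of 0.01 and 1 the test against a 1.5-fold change. In 1 the sign changed, MT-CO1, at -0.0329 with the abundance trend removed, where the mitochondrially encoded list also turned (camera, Benjamini-Hochberg adjusted p = 0.364). Against 10 lists, camera with an estimated correlation gave 4 and fry 5. The estimated correlation gave 0 with the abundance trend removed and 4 with the GC and length trend removed. The hepatocyte, cholesterol, cell cycle and lipogenesis lists passed in every alternative fixed before the data were examined, with camera's or fry's Benjamini-Hochberg adjusted p of at most 0.0468. Gene lists were not run with DESeq2. Where not stated, the cause of a difference was not tested. At this depth, genes changed 1.2-fold were recovered in 23.5% of cases in simulated data, so a change of that size was often not detectable. That rate is for genes picked from all abundances outside the lists. Smaller changes were called among abundant genes, since the higher genes other than VPS72 had a median rise of 15.9% at 296 CPM, against 21.3 CPM for all tested genes.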

Other observations

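The metallothionein test, the HEK293T test, the test of silent gene families the comparison of the sterol with the lipogenesis list and the medians of genes with and without an AU-rich motif were chosen after the results were seen, as were the genes named in the first paragraph.

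Among the other genes that rose, AGT, angiotensinogen, rose by 17.4% (log2 fold change 0.23 ± 0.04), A2M, alpha-2-macroglobulin, by 13.2%, SERPING1, the C1 inhibitor, by 15.7%, and ORM1, an acute phase protein, by 0.21 on the log2 scale. ABCA1, which exports cholesterol from cells, rose by 0.21 on the log2 scale, SKP2, a ubiquitin ligase subunit that targets the cell cycle inhibitor p27, by 17.9%, and TIMP3, an inhibitor of matrix metalloproteinases, by 18.0%. Among the lower genes, TIPARP, a target of the aryl hydrocarbon receptor, fell by 19.4%, GADD45B, a stress gene related to GADD45A, by 23.5%, PPP1R15A, which directs dephosphorylation of eIF2-alpha, by 18.1%, PPARGC1A, a coactivator of mitochondrial and gluconeogenic genes, by 24.4%, and MDM4, an inhibitor of p53, by 15.9%. In edgeR's quasi-likelihood test their Benjamini-Hochberg adjusted p ran from 0.00148 for TIPARP to 0.0489 for PPARGC1A.

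All 7 tested metallothionein genes had a negative log2 fold change, with a median of -0.54, and medians from -0.58 to -0.50 over 5 other scalings. Of these, 1, MT2A, passed over all genes, and MT1E (-0.43 ± 0.09) had an adjusted p of 0.0514 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The family was tested because MT2A had been seen to fall. Without MT2A the other 6 had a median of -0.56, with an unadjusted camera p of 2.3e-06 and 0.00837 with an estimated correlation. The members are near-identical paralogs between which reads could be shared.

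The sterol list's median exceeded that of the lipogenesis list by 0.0615 on the log2 scale (two-sided permutation of genes between the lists, p = 0.0129). By the same permutation test the difference was 0.0284 with the GC and length trend removed (p = 0.0651), 0.0471 without FLAG replicate 3 (p = 0.214) and 0.0318 without VPS72 replicate 1 (p = 0.197), so whether the lists differ stays open. Genes are not independent replicates, and the members of each list share regulators.

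With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 88 genes against at most 62 in another, with 1 of 10 as large, 60 higher and 28 lower against at most 60 in 1 direction, with 2 of 10 as large for each, and 2 genes of at least 2-fold against at most 5, with 2 of 10 as large. It gave 10 lists with the preset correlation against at most 6, with 1 of 10 as large. The other splits gave 1, 1, 6, 0, 2, 5, 3, 1 and 3 lists with the preset. With an estimated correlation they gave 0 each, and the real split 4. Those splits hold uneven mixes of the groups, so they are not free of a group difference. The split with 62 genes set FLAG replicates 1 and 3 and VPS72 replicate 3 against the other libraries. The median GC content of its genes was 63.5%, against 47.8% for all tested genes, and with the GC and length trend removed it gave 49 genes and the real split 391.

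The higher hepatocyte, cholesterol, lipogenesis and cell cycle lists could come from a trend with abundance or with GC content and length between the libraries. The medians of 4 of 4 lists lay above the central 95% of the medians of 10000 expression-matched random lists, and 4 of 4 passed camera with the GC and length trend removed, which argues against either trend as the whole cause. The oxidative phosphorylation, glycolysis and lipid droplet lists lay above it too, at percentiles 99.5, 99.32 and 99.31. The test thus does not set the 4 lists, taken up because they were higher, apart from those. The random lists were drawn gene by gene, so their spread leaves out correlation between list members. A response to VPS72 may account for the shift, as a hypothesis found in these data that these tests do not address. With the abundance trend removed and an estimated correlation their adjusted p were 0.0785 to 0.0924, and a difference between the groups in cell density or handling was not tested.

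The lower AP-1 and integrated stress lists both had medians below the central 95% of those of expression-matched random lists (2 of 2), which argues against an abundance trend as the whole cause. The random lists leave out correlation between list members, which was estimated at 0.21 for the AP-1 list and 0.0095 for the integrated stress list. Of the 27 lower genes with an annotated 3′ UTR, 63% carried an AU-rich TATTTAT motif, typical of short-lived mRNAs, against a median of 40.7% in lists matched on UTR length and expression (percentile 99.58). The 4317 tested genes with a motif had a median log2 fold change of -0.01 and the 7721 without one of 0.00. With an estimated correlation the AP-1 list had an adjusted p of 0.354 and the integrated stress list of 0.174 (camera, Benjamini-Hochberg). Carry-over of packaging cell RNA in the FLAG libraries cannot be told apart from an effect of VPS72, since 5 HEK293T genes were tested, with a median of -0.19 and a bootstrap 95% interval of -0.32 to 0.13, the most abundant at 17.2 CPM. These were 5 of 12 fixed HEK293T genes, and the rest did not pass the filter on low counts. The expression of VPS72 and the handling of the cells stay open as causes.

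Genes below 2 CPM had a median log2 fold change of -0.10. Thinning every library to the smallest total left -0.0896, which argues against depth as the cause. More background reads in the FLAG libraries may contribute and cannot be told apart, since 956 genes of families silent in liver held 560 counts in FLAG and 612 in VPS72 libraries, a ratio of shares of 0.985 (exact binomial 95% interval 0.877 to 1.11, which covers counting error only and not the spread between libraries), where the shift would need 0.936. Per library these families held 7.15 to 8.39 CPM of the unscaled totals in FLAG and 7.16 to 7.97 CPM in VPS72 libraries. The ratio of shares also uses unscaled totals, whereas 0.936 comes from the TMM-scaled fit. TMM factors were 1.008 to 1.013 in FLAG and 0.9886 to 0.9895 in VPS72 libraries, so scaled shares would have a higher ratio. The medians of the genes below 2 CPM against their mean over all 6 libraries were 0.12, 0.05 and 0.10 in the FLAG libraries and -0.00, -0.02 and -0.01 in the VPS72 libraries.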
